A study of Homo sapiens with 24 samples.

How the data were processed

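RNA-seq was performed on ectocervical biopsies of 12 participants, each sampled before exposure and 24 h after the last gel. Per the labels' protocols, libraries were made from 100 ng of RNA with a stranded poly(A) kit, TruSeq stranded mRNA, and sequenced as single reads of 75 bp. The deposited table holds raw read counts per Ensembl gene, not normalized, in 48 columns, 1 for each of 2 sequencing lanes of 24 libraries. The submitters' processing notes name cutadapt 1.9.1, STAR 2.4.2a, FastQC 0.11.5, featureCounts 1.5.0-p2 and the genome build GRCh37. The settings of these tools, and the strand setting of the counting, are not given in the sources used here. Without a known strand setting, genes that overlap an antisense partner or a neighbour are uncertain, which applies to LENG8-AS1, AC116552.1, LINC00894 and RSRP1. Counts of MUC20, of ribosomal protein genes, of histone genes and of mitochondrially encoded genes are uncertain as well, since these have near-identical copies elsewhere in the genome. Coordinates are those of the deposited table on GRCh37 and span each gene from its first to its last annotated exon.

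The 2 lanes of a library differed by slightly more than sampling noise (chi-square per degree of freedom 1.00 to 1.05, mean 1.03, above 1 in each of the 24 libraries) and were summed. Gene symbols were taken from GENCODE release 29 by Ensembl identifier, which matched 52338 of 57905 identifiers. Y-linked genes, XIST and TSIX (497 in all) were left out before library sizes were computed, leaving 57408. Rows without a symbol stayed in the library sizes and held 0.388 to 1.01% of the counts. Total counts ranged from 26273435 to 30533890 per library. At this depth a gene at 1 CPM rests on 26.3 to 30.5 counts. How counting error compares with the spread between participants was not tested.

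Groups follow the sample titles, which give 12 baseline, 9 after PC-6500 and 3 after placebo. The time point label of the 3 after-placebo samples reads as PC-6500 instead. The title was used because the time point label would leave no placebo group, and 1 comparison that ignores the arm, over all 12 participants, was made for this reason. Each participant gave a baseline and an after-gel sample, so gene p-values within participants set the change against how far it varied between people. Those between baselines set the difference between arms against the spread between people. After-gel and baseline libraries pair because they come from the same donor, as the series' design text states. Deviations from the group means correlated within 9 of the 12 pairs at over 0.1 (range −0.11 to 0.59, median 0.43), and 9 of the 12 after-gel libraries lay closest to their own baseline.

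Counts were tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood test with TMM scaling and the participant as a block. Genes were kept by filterByExpr over the 3 groups, with a minimum count of 10 and a minimum total of 15, which left 18652. One fit with a term for after PC-6500 and one for after placebo gave the change in each arm and the difference between the changes, with 10 residual degrees of freedom. A separate fit gave the change over all 12 participants, and a fit on the 12 baselines compared the arms before exposure on 17736 genes. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. CPM values use TMM library sizes and are given as mean ± SD, log2 changes with the standard error (SE) of the fit.

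A total of 39 gene lists with 799 genes were fixed before the data were examined, as were the groups, tests and most of the alternative settings. They cover epithelium, immune response, hormone response, general tissue functions, other cell types and technical signals. Fixed as technical were mitochondrially encoded transcripts, ribosomal proteins, heat shock, immediate early genes and replication-dependent histones, the last for poly(A) selection. Of these genes 9 had no matching symbol. Lists with fewer than 5 tested members (melanocytes and red blood cells, 3 each) were left out, so 37 were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and a list was called at an adjusted p under 0.05. At this preset the p of camera ranks the genes of a list against other genes and mainly measures spread over genes, not over participants. With a correlation estimated for each list, camera called none, with all participants or under the other list settings, and that p is given beside the calls. fry tested whether the genes of a list moved, on balance, one way. Each list was also scored per library as the mean log2 CPM of its members with a prior count of 2. Score changes were tested by an exact sign-flip test within an arm and an exact permutation of the arm over 220 assignments. The smallest possible p is 0.00391 for 9 pairs, 0.25 for 3 pairs and 0.00455 between arms, so that no score could pass in the placebo arm.

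Genes were named by a fixed rule. For PC-6500 and for all participants the rule took up to 10 higher and 10 lower genes past the threshold that moved the same way in at least 7 of 9 or 9 of 12 participants. For placebo and for the difference it took up to 5 higher and 5 lower, for placebo with the same direction in 3 of 3. Where fewer than 10 or 6 genes passed, it took the genes of smallest unadjusted p up to that number, as values that did not pass. From each called list it took the 3 members of smallest p, and from each epithelial or immune list not called after PC-6500 the 2 members of smallest p. HLA genes, immunoglobulin and T cell receptor segments, pseudogenes and genes without a symbol were not named. The rule gave 109 genes. One result is not reported here.

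The code was tested on simulated counts drawn from the means and library sizes of the real 18652 genes, with 50 genes changed at each of 4 fold sizes. Each gene was drawn independently, so the simulation holds no shift of tissue composition between the 2 biopsies of a participant. The shares recovered therefore need not hold for the real libraries. For the change after PC-6500 it recovered 34% of genes changed 1.5-fold, 64% of those changed 2-fold, 76% at 3-fold and 84% at 4-fold, with 6 false calls. For placebo it recovered 4%, 28%, 62% and 62%, with 2 false calls. For the difference between arms, with the change placed in the PC-6500 arm, it recovered 6%, 22%, 44% and 52%, with 4 false calls.

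Alternatives were DESeq2 1.42.0, limma voom, limma voom with the participant as a random effect, fits without the block, other size factors, other filters on low counts, each lane alone, a non-robust fit, each arm fitted alone, the arm taken from the time point label, a composition covariate (squamous minus fibroblast score), fry and an estimated correlation for the lists, and each participant left out in turn. With the arm taken from the time point label, the comparison equals that over all participants, so its values were taken over without another fit. For list scores, the median over members and a prior count of 0.5 were tried. A fit with the columnar score as covariate and fits without the 3 participants who had a columnar-rich library were added after the data had been seen, as was the estimated correlation together with the other list settings. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.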

Results

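Gene expression was measured by RNA-seq in biopsies of the ectocervix, the outer part of the cervix, which is covered by stratified squamous epithelium. The biopsies came from 12 participants of a phase 1 trial of PC-6500, a vaginal gel that carries griffithsin in carrageenan. Griffithsin is a lectin from a red alga that binds mannose-rich glycans on the HIV envelope, and carrageenan is a sulfated seaweed polysaccharide used to thicken gels. Each participant gave a biopsy before exposure and another 24 h after the last gel, which made 24 libraries, 12 at baseline, 9 after PC-6500 and 3 after placebo gel. Total counts per library ranged from 27534386 to 30533890 at baseline, from 26273435 to 30088369 after PC-6500 and from 27356629 to 30369074 after placebo. Levels are given in CPM, counts relative to the library size, as mean ± SD over the participants of an arm (n = 9 for PC-6500, n = 3 for placebo). Between 22673 and 26957 genes had at least 1 count in a library, and the 10 most abundant genes took 12.4 to 23.5% of the counts.

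Of the variance between libraries, the first principal component took 40.7%, and 3 libraries lay far out on it, with component scores of 95.4, 141 and 179 against 36.2 for the next library. The same 3 libraries had a mean log2 CPM above 6 over the list of endocervical columnar epithelium, the mucus-forming lining of the inner cervix, while 18 libraries were below 2. The 3 in between were after PC-6500 replicate 1 (3.77, from 0.94 at the participant's own baseline), replicate 2 (4.89, from 7.33) and replicate 3 (2.63, from 7.60). Other lists set the same 3 apart as well, with scores of 5.48 to 6.10 for complement and coagulation against at most 4.41 in the other libraries, 4.96 to 5.61 for NF-kB targets against at most 3.99, and 2.49 to 6.76 for B and plasma cells against at most 2.39. The 3 far out were baseline replicates 2 and 5 and after PC-6500 replicate 4, all in the PC-6500 arm. The columnar score of that arm was 2.31 ± 2.93 at baseline and 2.49 ± 2.63 after gel (n = 9), and that of the placebo arm 0.62 ± 0.25 and 0.56 ± 0.43 (n = 3).

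**Figure D1:**
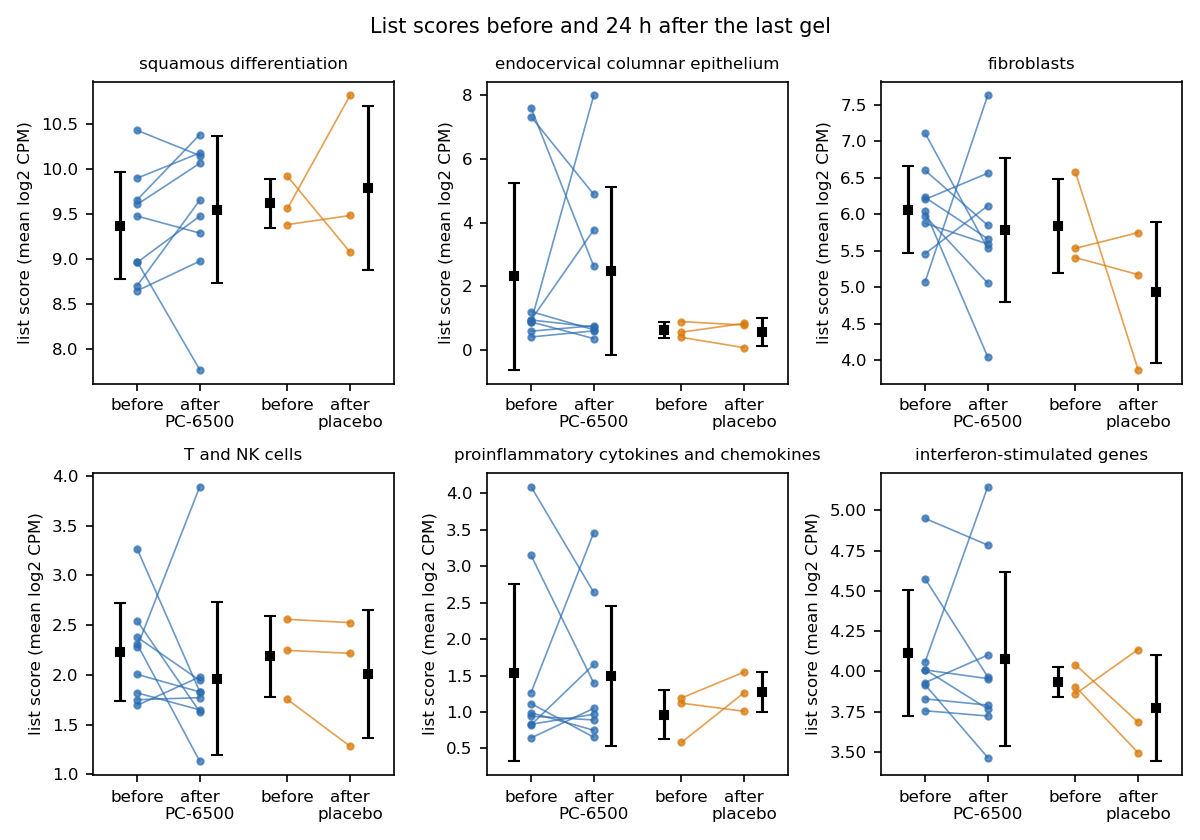
List scores, the mean log2 CPM over the members of a gene list, of each participant before and 24 h after the last gel for 6 lists, with lines joining the biopsies of a participant (blue, PC-6500, n = 9; orange, placebo, n = 3) and black squares with bars for the mean ± SD. The columnar score was above 6 in 3 libraries of the PC-6500 arm, and in no panel do all 9 PC-6500 participants move the same way.

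The first comparison asked what 24 h after the last PC-6500 gel looked like against the participants' own baseline. CCNL2, a cyclin that acts in pre-mRNA splicing (ENSG00000221978, GRCh37 chromosome 1, 1321091 to 1334708), was at 103 ± 18.3 CPM at baseline and 133 ± 20.3 CPM after gel (log2 difference 0.37, SE 0.07) and higher in 9 of 9 participants. NEAT1, the long noncoding RNA that builds nuclear paraspeckles (ENSG00000245532, chromosome 11, 65190245 to 65213011), was at 529 ± 261 and 720 ± 239 CPM (log2 difference 0.53, SE 0.11) and higher in 8 of 9. PTPRZ1, a receptor tyrosine phosphatase (ENSG00000106278, chromosome 7, 121513143 to 121702090), was at 30.7 ± 10.4 and 22.1 ± 9.81 CPM (log2 difference −0.53, SE 0.11) and lower in 7 of 9. None of 18652 genes passed in edgeR, where the smallest adjusted p was 1.00 and 790 genes (480 higher, 310 lower, 4.24% of those tested) had an unadjusted p under 0.05. That number was 1859 without the participant of after PC-6500 replicate 4 and 511 without that of replicate 3, with 0 genes called in both fits. limma voom called 0 genes with 860 at an unadjusted p under 0.05, and DESeq2 called 3, all higher, with 895. The 3 were NEAT1 and CCNL2 (adjusted p = 0.00180 each in DESeq2) and 1 gene that the naming rule excludes. NEAT1 and CCNL2 were also higher in 3 of 3 placebo participants.

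The other genes of smallest p after PC-6500 did not pass either. PARP6, a mono-ADP-ribosyltransferase, was at 25.5 CPM at baseline and 30.7 CPM after gel (log2 difference 0.28), the matrix gene THBS3 at 18.1 and 22.5 CPM (0.32), and the mRNA export factor NXF1 at 66.3 and 76.4 CPM (0.21), each higher in 9 of 9 participants. The antisense gene LENG8-AS1 had a log2 difference of 0.98, AC116552.1 of 1.67, LINC00894 of 0.58 and RSRP1 of 0.28, and all 4 are uncertain because they overlap other genes. FLG, which encodes the filaggrin of cornifying epithelium, was at 209 ± 189 CPM at baseline and 448 ± 335 CPM after gel (log2 difference 1.12, SE 0.34) and higher in 7 of 9 participants. The 95% interval of the log2 change lay within a 2-fold change either way for 15264 of 18652 genes (81.8%), and the median SE was 0.15.

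**Figure D2:**
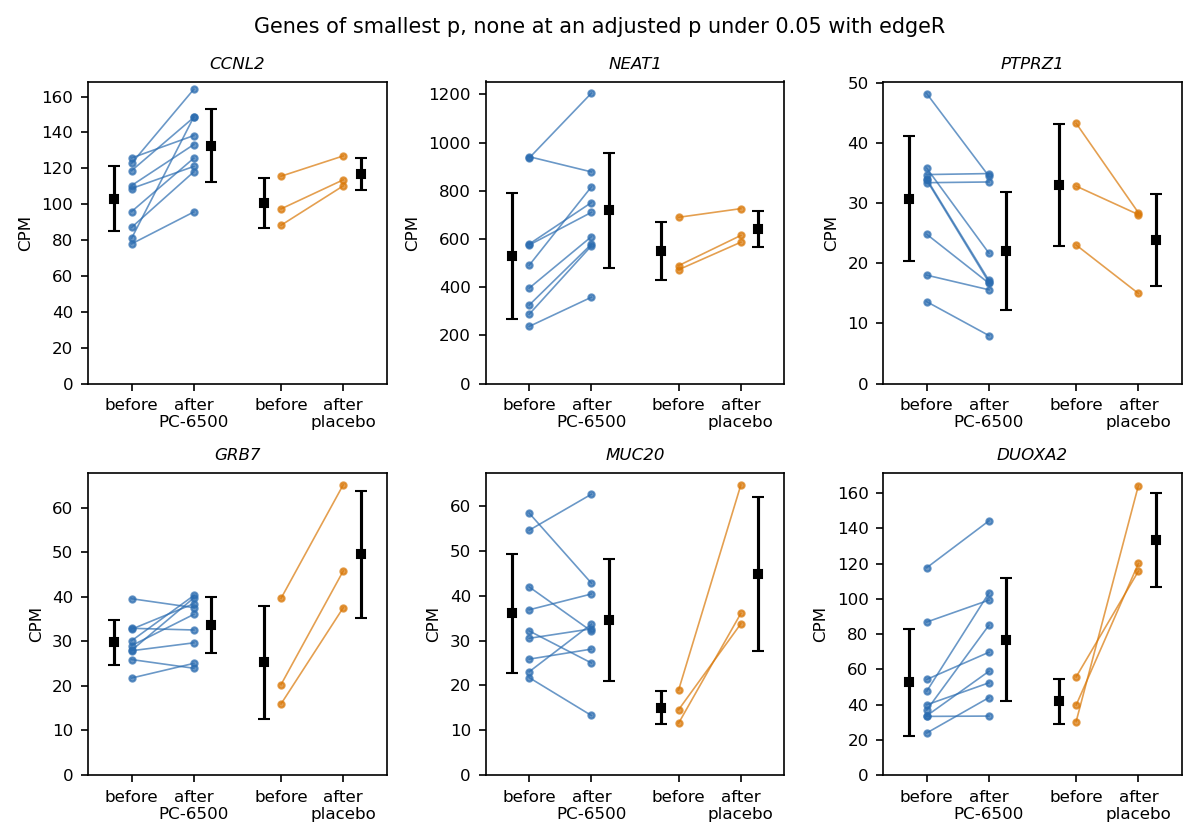
CPM of the 3 named genes of smallest p after PC-6500 (CCNL2, NEAT1, PTPRZ1) and after placebo (GRB7, MUC20, DUOXA2) in each participant before and after gel (blue, PC-6500, n = 9; orange, placebo, n = 3), with black squares and bars for the mean ± SD. MUC20 was higher after gel in all 3 placebo participants (15.03 to 44.9 CPM on average) and at 36.2 and 34.5 CPM in the PC-6500 arm, and none of the 6 genes passed an adjusted p of 0.05 in edgeR.

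Of the 37 gene lists, camera called 7 after PC-6500, 6 lower and 1 higher. Among the lower ones, mitochondrially encoded transcripts, ribosomal proteins, immediate early genes and heat shock had been fixed as technical signals. All 13 mitochondrially encoded transcripts were lower (median log2 change −0.20, adjusted p = 3.87e-07), among them MT-ND6 (89.7 and 71.8 CPM, −0.28), MT-ND3 (−0.25) and MT-ATP8 (−0.21). Of 30 ribosomal protein genes 29 were lower by a small amount (median −0.08, adjusted p = 3.77e-05), led by RPS27A (−0.19), RPL30 (−0.18) and RPS23 (−0.16). NF-kB targets were lower for 16 of 19 genes (median −0.22, adjusted p = 0.00883), with IRAK2 at −0.37, RELB at −0.32 and NFKBIA at −0.22, and immediate early genes for 18 of 26 (median −0.13, adjusted p = 0.00883), with FOSB at −0.75, EGR1 at −0.56 and CYR61 at −0.38. Markers of T and NK cells were lower for 24 of 25 genes (adjusted p = 0.0206), with CD8A at 12.9 CPM before and 9.73 CPM after gel (log2 difference −0.50), CD2 at −0.37 and KLRB1 at −0.43. Heat shock genes were lower for 10 of 13 (median −0.05, adjusted p = 0.0299), with HSP90AA1 at 736 and 654 CPM (−0.18) and HSPE1 at −0.28. The ciliated cell list was called higher (4 of 7 genes, median 0.04, mean 0.11, adjusted p = 0.00883), with CAPS at 0.32, DNAH9 at 0.51 and PIFO at −0.14. In after PC-6500 replicate 4 alone these genes changed by 3.99, 4.97 and 6.08 on the log2 scale, the last opposite in sign to the fitted value. Each of the 7 calls had an adjusted p = 0.984 with an estimated correlation, fry called none (lowest adjusted p = 0.999), and 0 members passed when adjusted over the list alone.

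Only the mitochondrial call held without each of the 9 participants in turn. Without the participant of after PC-6500 replicate 4, the ciliated list turned lower (adjusted p = 0.0248) and the calls of ribosomal proteins (0.149), immediate early genes (0.0812) and heat shock (0.622) ended, and the number of called lists rose to 24, of which 20 were not called with all 9. Without replicate 2 the adjusted p was 0.831 for NF-kB targets, 0.855 for T and NK cells and 0.831 for immediate early genes. Without replicate 3 it was 0.254 for NF-kB targets, 0.308 for T and NK cells and 0.254 for heat shock. Without replicate 6 it was 0.305 for T and NK cells, and heat shock was at 0.0541 without replicate 5 and 0.0580 without replicate 9. Without the 3 participants who had a columnar-rich library, NF-kB targets (0.626), ciliated cells (0.626) and heat shock (0.683) were not called, and immediate early genes were called higher (0.0173).

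With all 9 participants no list of the epithelial barrier was called after PC-6500, but leaving out 1 participant changed that for 4 lists. Squamous differentiation genes were higher for 28 of 38 (median 0.09, adjusted p = 0.202) and the score changed by 0.18 on average (95% interval −0.32 to 0.68, n = 9). Genes of epithelial junctions split evenly, 16 higher and 16 lower (adjusted p = 0.677), with a score change of −0.01 (−0.35 to 0.33). Of the basal epithelium 13 of 16 genes were higher (median 0.08, adjusted p = 0.335), of epidermal proteases and inhibitors 12 of 18 (adjusted p = 0.677), and of mucins and glycosylation 6 of 19 (adjusted p = 0.237). Antimicrobial peptides and mucosal defence genes were higher for 7 of 17 (adjusted p = 0.677), with RNASE7 at a log2 difference of 0.52, and the score changed by −0.03 (−0.73 to 0.68). No member of any of these lists passed when adjusted over the list alone. Without the participant of after PC-6500 replicate 4, squamous differentiation (adjusted p = 4.92e-07), basal epithelium and epithelial junctions (0.00220 each) and epidermal proteases and inhibitors (0.00604) were called higher, and squamous differentiation also without that of replicate 9 (0.0450). The fit without replicate 4 holds 2 columnar-rich libraries, both at baseline, and in it endocervical columnar epithelium (1.17e-10), B and plasma cells (4.77e-05) and complement and coagulation (0.000110) were called lower. Without the 3 participants who had a columnar-rich library, squamous differentiation (0.00144), basal epithelium (0.00429) and epithelial junctions (0.0351) were called higher. With an estimated correlation none of the 37 lists was called in any of these fits (lowest adjusted p = 0.427).

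Inflammatory and immune lists beyond the called ones lay lower or near 0. Proinflammatory cytokines and chemokines were lower for 23 of 36 genes (adjusted p = 0.160) with a score change of −0.04 (95% interval −0.95 to 0.86), and CCL2 was lower in 8 of 9 participants (log2 difference −0.63). Interferon-stimulated genes were lower for 26 of 45 (adjusted p = 0.6996), with a median of −0.05 while camera ranked the list as higher, and the score changed by −0.04 (−0.41 to 0.33). The list of HIV entry receptors and target cell markers was lower for 10 of 15 genes (adjusted p = 0.366), with CD69 at −0.52 and CXCR6 at −0.44, and the score changed by −0.18 (−0.64 to 0.27). Antigen processing (10 of 11 lower, adjusted p = 0.0571), fibroblasts (18 of 20 lower, adjusted p = 0.0571), neutrophils (12 of 13 lower, adjusted p = 0.112) and macrophages and dendritic cells (16 of 21 lower, adjusted p = 0.112) were not called with all 9 participants either. Without the participant of after PC-6500 replicate 4 these 7 lists were called lower, with adjusted p of 0.000326 for cytokines and for antigen processing, 0.00773 for interferon-stimulated genes, 0.00617 for the HIV list, 5.10e-06 for fibroblasts, 9.06e-07 for neutrophils and 4.92e-07 for macrophages and dendritic cells. Called lower in the same fit were endocervical columnar epithelium (1.17e-10) and B and plasma cells (4.77e-05). Antigen processing was also called lower without replicate 1 (0.00935), 7 (0.0364) or 8 (0.0287), fibroblasts without 1 (0.00856) or 9 (0.00751), and cytokines without 1 (0.0431). Without the 3 participants who had a columnar-rich library, antigen processing (0.0259), fibroblasts (0.000274), the HIV list (0.0443) and macrophages and dendritic cells (0.00104) were called lower. No list was called in these fits with an estimated correlation (lowest adjusted p = 0.427). None of the 37 score changes passed the exact sign-flip test over 9 pairs, the lowest p being 0.0664 (adjusted p = 0.961) for the mitochondrial score, at −0.20 (−0.45 to 0.05).

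**Figure D3:**
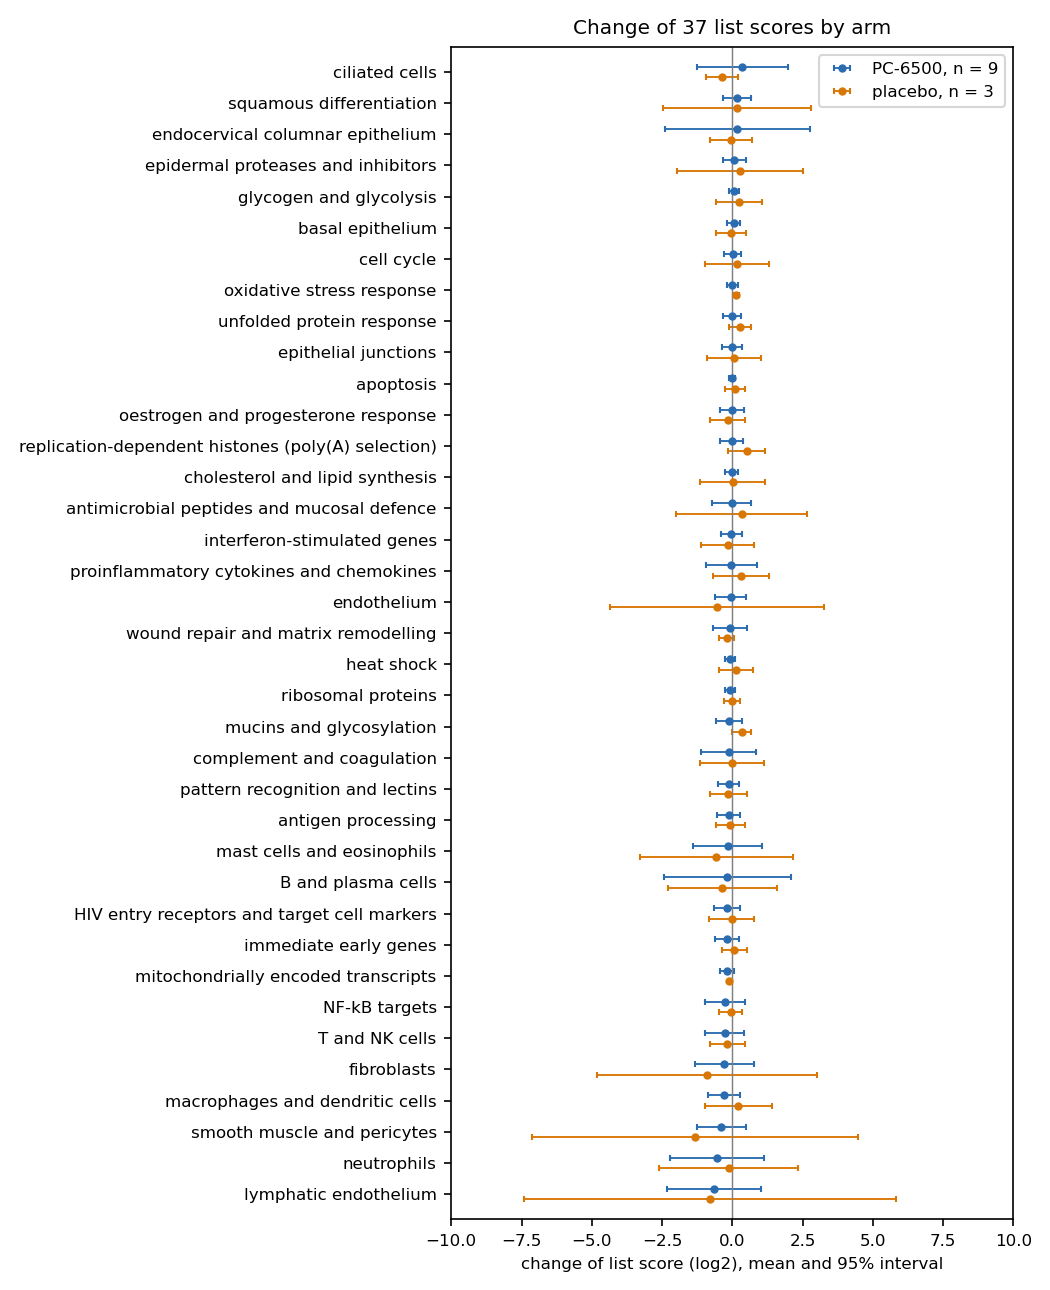
Change of each of the 37 list scores, after gel minus own baseline on the log2 scale, as mean and 95% interval by arm (blue, PC-6500, n = 9; orange, placebo, n = 3), ordered by the PC-6500 mean. The interval of the PC-6500 arm includes 0 for every list, and the intervals of the placebo arm are wide for stromal lists such as smooth muscle and pericytes (mean −1.33).

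The second comparison took the 3 placebo participants against their own baseline, over the same interval as in the PC-6500 arm. GRB7, an adaptor of receptor tyrosine kinases (ENSG00000141738, chromosome 17, 37894180 to 37903544), was at 25.3 ± 12.6 CPM at baseline and 49.5 ± 14.2 CPM after gel (log2 difference 1.04, SE 0.14). MUC20, a membrane mucin (ENSG00000176945, chromosome 3, 195447753 to 195467994), was at 15.03 ± 3.71 and 44.9 ± 17.3 CPM (1.54, SE 0.21), and DUOXA2, which matures the peroxide-producing oxidase DUOX2 (ENSG00000140274, chromosome 15, 45406519 to 45410619), at 41.9 ± 12.8 and 133 ± 26.9 CPM (1.69, SE 0.27). PIK3IP1 (21.9 and 45.8 CPM, 1.06) and MAP2K1 (51.3 and 82.7 CPM, 0.70) were also higher and RASSF9 lower (1.53 and 0.396 CPM, −2.01), and all 6 moved the same way in 3 of 3 participants. In edgeR 0 genes passed, with 1053 at an unadjusted p under 0.05 (615 higher, 438 lower), or 497 without the participant of after placebo replicate 3. GRB7 and MUC20 came nearest (adjusted p = 0.0685), followed by DUOXA2 and PIK3IP1 (0.186), MAP2K1 (0.233) and RASSF9 (0.355). limma voom called 0 (1063 at an unadjusted p under 0.05) and DESeq2 called 95, 81 higher and 14 lower, with GRB7 (adjusted p = 2.74e-09), MUC20 (6.16e-08), DUOXA2 (1.65e-06), PIK3IP1 (6.03e-05) and MAP2K1 (7.28e-05) among them.

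Camera called 9 lists after placebo, 6 higher and 3 lower. All 20 genes of the unfolded protein response were higher (median 0.25, adjusted p = 0.000497), with the chaperone HSPA5 at 361 CPM before and 510 CPM after gel (log2 difference 0.51), TRIB3 at 0.78 and CALR at 0.33. Glycogen and glycolysis genes were higher for 16 of 20 (median 0.25, adjusted p = 0.000768), with PFKFB3 at 112 and 238 CPM (1.09), ALDOA at 0.52 and GAPDH at 0.52. Mucins and glycosylation genes were higher for 13 of 19 (median 0.24, adjusted p = 0.00105), with MUC21 at 0.96 and FUT3 at 0.68, and squamous differentiation genes for 28 of 38 (median 0.36, adjusted p = 0.00572), with ECM1 at 748 and 1510 CPM (1.14), PPL at 0.79 and SPRR2D at 1.06. Cell cycle genes were higher for 27 of 30 (median 0.14, adjusted p = 0.0239), with CDC20 at 0.44 and TK1 at 0.43, and all 7 replication-dependent histones as well (median 0.55, adjusted p = 0.0239), led by HIST1H4H (0.97). The histone list had been fixed as a technical signal of poly(A) selection. The lower lists were stromal. Smooth muscle and pericyte genes were lower for 14 of 15 (mean −1.22, adjusted p = 2.97e-05), with ACTG2 at −3.46, fibroblast genes for 19 of 20 (median −0.76, adjusted p = 0.000497), with FBN1 at −1.77 and DCN at −1.04, and endothelial genes for 12 of 14 (median −0.62, adjusted p = 0.0239), with ROBO4 at −1.12 and ESAM at 0.58. With an estimated correlation the adjusted p was 0.652 for mucins and glycosylation and 0.981 for the other 8. fry called none in 1 direction (lowest adjusted p = 0.428), and its test for change in either direction called apoptosis (adjusted p = 0.00431).

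Over the placebo lists, 10 members passed when adjusted over the list alone, 4 of the proinflammatory cytokines and chemokines, 3 of apoptosis, and 1 each of glycogen and glycolysis, mucins and glycosylation, and endocervical columnar epithelium. IL36G, an epithelial alarm cytokine, was at 1.18 CPM before and 7.03 CPM after placebo (log2 difference 2.59). No score could pass with 3 pairs, where the smallest exact sign-flip p is 0.25. Of the 37 scores 8 moved the same way in 3 of 3 participants, where chance alone gives about 1 in 4. Higher were histones (mean change 0.51), mucins and glycosylation (0.33), the unfolded protein response (0.29) and oxidative stress response (0.13), and lower were ciliated cells (−0.37), wound repair and matrix remodelling (−0.20), T and NK cells (−0.18) and mitochondrially encoded transcripts (−0.12).

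Of the 9 placebo calls only that of the unfolded protein response held without each of the 3 participants in turn. Without the participant of after placebo replicate 3 the adjusted p was 0.958 for fibroblasts, 0.871 for smooth muscle, 0.523 for glycogen and glycolysis, 0.0670 for mucins and glycosylation and 0.103 for histones, squamous differentiation turned lower (0.449), and the endothelial list was called higher (0.0292). Without replicate 2 histones were at 0.177 and cell cycle turned lower (0.260). Lists not called with all 3 gained a call too, 4 without replicate 1, 5 without replicate 2 and 1 without replicate 3. In these fits 0 lists were called with an estimated correlation (lowest adjusted p = 0.478).

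The third comparison set the change after PC-6500 against the change after placebo, the contrast that the randomized design provides. MUC20 had the smallest p, at 36.2 ± 13.3 CPM at baseline and 34.5 ± 13.6 CPM after PC-6500 (n = 9) against 15.03 ± 3.71 and 44.9 ± 17.3 CPM in the placebo arm (n = 3), a log2 difference of the changes of −1.63 (SE 0.24). GRB7 (−0.87), MAP2K1 (−0.72), the fatty acid oxidation enzyme ACADM (−0.71) and the mucin-type glycosyltransferase GALNT12 (−1.24) had lower changes with PC-6500 too, and the matrix gene THBS4 a higher one (3.39). In edgeR 0 genes passed, the smallest adjusted p being 0.301 for MUC20, and 617 genes (248 higher, 369 lower) had an unadjusted p under 0.05, or 372 without the participant of after placebo replicate 3. limma voom called 0 (654 at an unadjusted p under 0.05) and DESeq2 called 26, 6 higher and 20 lower, with MUC20 (adjusted p = 5.01e-06), GRB7 (0.000762), MAP2K1 (0.00317), ACADM (0.00556) and GALNT12 (0.0147) among them. MUC20 passed in edgeR without the participant of after PC-6500 replicate 4 (log2 −1.71, adjusted p = 0.0477).

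Camera called 11 lists in this contrast, 8 with a lower and 3 with a higher change under PC-6500 than under placebo. Among the lower ones, immediate early genes, histones and ribosomal proteins had been fixed as technical signals. Lower were mucins and glycosylation (16 of 19 genes, median −0.42, adjusted p = 0.000271), with ST3GAL4 at −0.61, and the unfolded protein response (20 of 20, median −0.29, adjusted p = 0.000411). Lower as well were immediate early genes (20 of 26, adjusted p = 0.00283), with ZFP36 at −0.76 and JUNB at −0.64, glycogen and glycolysis (16 of 20, adjusted p = 0.0150), with PYGL at −0.47, and histones (7 of 7, adjusted p = 0.0150). The lower lists of least distance were apoptosis (14 of 20, adjusted p = 0.0210), with PMAIP1 at −0.92 and GADD45A at −0.70, cell cycle (28 of 30, adjusted p = 0.0210), with PCNA at −0.22, and ribosomal proteins (27 of 30, adjusted p = 0.0448), with RPL18 at −0.18. Higher were smooth muscle and pericytes (13 of 15, median 0.78, adjusted p = 0.000411), with ACTA2 at 1.12, fibroblasts (16 of 20, median 0.53, adjusted p = 0.0210), with SFRP4 at 1.51 and COL5A1 at 0.90, and endothelium (12 of 14, median 0.47, adjusted p = 0.0448). With an estimated correlation the adjusted p was 0.254 for mucins and glycosylation and 0.819 for the other 10. fry called none (lowest adjusted p = 0.272). Adjusted over the list alone, 1 member passed in mucins and glycosylation and 1 in endocervical columnar epithelium. No list score differed between the arms by exact permutation, the lowest p being 0.173 (adjusted p = 0.985) for the histones.

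Mucins and glycosylation and the unfolded protein response kept their calls in this contrast without each of the 12 participants in turn, and the other 9 lists did not. Without the participant of after placebo replicate 3, smooth muscle (adjusted p = 0.571), fibroblasts (0.345) and glycogen and glycolysis (0.951) turned direction without a call, endothelium was called lower (0.00871), and ribosomal proteins were at 0.473. Without after placebo replicate 2, cell cycle turned (0.233) and apoptosis (0.174) and histones (0.0872) were not called, and without replicate 1 ribosomal proteins were at 0.162. Single participants of the PC-6500 arm ended calls too. These were replicate 1 for fibroblasts and endothelium (0.0629 each) and ribosomal proteins (0.153), replicate 2 for immediate early genes (0.0893), and replicate 3 for apoptosis (0.0964). Replicate 4 did so for fibroblasts (0.330), endothelium (0.117), glycogen and glycolysis (0.0808), cell cycle (0.141) and ribosomal proteins (0.487), and replicate 5 for endothelium (0.0787) and ribosomal proteins (0.0969). Replicate 6 did so for cell cycle (0.0783), replicate 7 for endothelium (0.0518) and ribosomal proteins (0.131), replicate 8 for cell cycle (0.124), and replicate 9 for fibroblasts (0.0722), endothelium (0.0892) and cell cycle (0.0660). Lists not called with all 12 gained a call as well, at most 10, without the participant of after PC-6500 replicate 4. With an estimated correlation 0 lists were called in these fits (lowest adjusted p = 0.168).

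The fourth comparison pooled all 12 participants, whatever the gel, against their own baseline. PTPRZ1 was lower in 10 of 12 (log2 difference −0.52), CCNL2 higher in 12 of 12 (0.33), NEAT1 in 11 (0.45) and DUOXA2 in 12 of 12 (0.85). The cytokine-induced inhibitor CISH was higher in 12 of 12 (0.43), the stress gene GADD45A in 10 (0.67), the kinase gene SRMS in 11 (1.92) and the sodium channel gene SCNN1D in 11 (0.55), and the interferon gamma receptor gene IFNGR1 was lower in 11 (−0.25). In edgeR 0 genes passed, each of the genes named here having an adjusted p of 0.688, and 1223 genes (672 higher, 551 lower) had an unadjusted p under 0.05, or 2848 without the participant of after PC-6500 replicate 4. limma voom called 0 (1284 at an unadjusted p under 0.05). DESeq2 called 34, 25 higher and 9 lower, with CCNL2 (adjusted p = 0.000621), NEAT1 and PTPRZ1 (0.00331), CISH and DUOXA2 (0.00890), GADD45A (0.00977), IFNGR1 (0.0185) and SCNN1D (0.0257) among them.

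The arms were also compared at baseline, before any gel. In edgeR 0 of 17736 genes differed between the 9 baselines of the PC-6500 arm and the 3 of the placebo arm, with a smallest adjusted p of 0.470 and 1265 genes (574 higher, 691 lower) at an unadjusted p under 0.05. Without baseline replicate 4 it called 1 gene with near-identical copies, and 593 had an unadjusted p under 0.05. DESeq2 called 49, 29 higher and 20 lower in the PC-6500 arm. The score of mucins and glycosylation was 5.64 ± 0.48 in the PC-6500 arm (n = 9) and 4.90 ± 0.09 in the placebo arm (n = 3), and the difference did not pass by exact permutation over 37 lists (p = 0.0364, adjusted p = 0.817). MUC20, the gene with the smallest p in the contrast of changes, was at 36.2 ± 13.3 and 15.03 ± 3.71 CPM at baseline in the same order.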

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

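The test of ciliated cells, both tests of a gel effect on columnar transcripts, the test of columnar tissue behind the mitochondrial change, and both tests of the stromal lists were chosen only after the result was seen. The ciliated test was run first and left the question open, and the second columnar list was written after that, with its prediction before its own result. The list of nuclear-retained transcripts was written after NEAT1 and CCNL2 had been seen, holds neither of them, and had its prediction written before its result.

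The first pattern is the 3 libraries rich in endocervical columnar transcripts, baseline replicates 2 and 5 and after PC-6500 replicate 4. MUC5B (ENSG00000117983, GRCh37 chromosome 11, 1244296 to 1283406), a secreted mucin, was at 1304 to 4456 CPM in them and at no more than 2.35 CPM in the 18 libraries with a columnar score under 2, and PIGR (890 to 2313 against at most 0.804 CPM), BPIFB1 (597 to 2436 against 0.383) and WFDC2 (582 to 1243 against 2.12) behaved alike, while KRT19 of the same list reached 753 CPM in those 18. A gel effect as the whole cause is excluded, since 2 of the 3 were taken at baseline, but an effect on columnar transcripts after PC-6500 stays open: the 3 libraries with scores between (3.77, 4.89 and 2.63, from 0.94, 7.33 and 7.60 at baseline) were all after PC-6500, and over 9 participants the score changed by 0.18 (95% interval −2.40 to 2.75, exact sign-flip p = 0.926). Columnar tissue in these biopsies is a candidate explanation, as 8 of 11 tested members of a second columnar list with no shared gene were higher in each of the 3 than in any of the 18. Whether ciliated cells came along stays open, with 3 of 7 ciliated genes higher in each of the 3.

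The second pattern is the lower level of mitochondrially encoded transcripts with higher NEAT1 and CCNL2 after PC-6500. It was also seen after placebo, where NEAT1 and CCNL2 were each higher in 3 of 3 participants. The mitochondrial score was lower in 3 of 3 there (mean change −0.12). A shift towards nuclear RNA through RNA handling or quality is a candidate explanation. A response of the tissue to the gel may give the same pattern. A separate list of 23 nuclear-retained transcripts changed by 0.188 on the log2 scale (95% interval 0.05 to 0.33). It was higher in 8 of 9 participants (exact sign-flip p = 0.00781). The adjusted p of 0.0156 covers only this list and the mitochondrial list, not all the gene lists scored above. The list was written after NEAT1 and CCNL2 had been seen in the same libraries, so it is not independent support. Across participants, the change of the nuclear-retained list showed no clear relation to that of the mitochondrial score (values below), which adds no support for such a shift. With placebo this list changed by 0.04 (higher in 3 of 3), the difference between arms did not pass (0.15, exact permutation p = 0.177), and an effect of PC-6500 on the mitochondrial score beyond placebo stays open (exact arm permutation p = 0.673). Columnar tissue also stays open, as the mitochondrial score without the 3 participants with columnar-rich libraries changed by −0.133 (95% interval −0.34 to 0.08, lower in 5 of 6, exact p = 0.156). Over 12 participants and 2 relations examined, the change of the mitochondrial score did not follow that of library size (Pearson r = −0.117, permutation p = 0.754, adjusted p = 0.923; Spearman rho = −0.105, p = 0.747; r = 0.0414 without the 2 farthest) or of the nuclear list (r = −0.0248, permutation p = 0.923; rho = −0.231, p = 0.474; r = −0.542 without the 2 farthest).

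The third pattern is the lower fibroblast, smooth muscle and endothelium lists after placebo. After placebo replicate 3 had the largest falls, at −2.71 for the fibroblast score, −3.98 for smooth muscle and −2.29 for endothelium. Without this participant 0 of the 3 lists were lower and called, which restates the pattern, since the biopsy was chosen for its falls, and decides nothing about its cause. Less stroma in 1 biopsy and an effect of the placebo gel cannot be told apart with 3 pairs, where 0 of the 3 scores were lower in 3 of 3 participants.

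Other splits of the participants were compared with the real one, which is included in each count. For genes at an unadjusted p under 0.05, 31 of 100 splits reached the 790 of the PC-6500 comparison (highest other 3660), 45 of 100 the 617 of the difference between arms (4584), 16 of 100 the 1223 over all participants (3640) and 23 of 100 the 1265 between baselines (3642), so chance is not excluded for any of these. For lists called by camera, 95 of 100 splits reached the 7 of PC-6500 (highest other 32, median 15) and 74 of 100 the 11 of the difference (highest 29, median 17), and chance is not excluded there either. For placebo the 4 possible splits are too few for a share under 0.05, where 1, the real one, reached 1053 genes (highest other 824) and all 4 reached 9 lists (highest other 16). Other splits called up to 2 genes for PC-6500, 0 for placebo, 22 for the difference, 5 over all participants and 1024 between baselines, against 0 in each real split. Why some splits called so many genes was not tested.

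Single participants stood apart from the rest of the PC-6500 arm in 7 of 37 list scores and 7 of 55 named genes. After PC-6500 replicate 4 had 9 of them, with score changes of 5.67 for ciliated cells, 3.46 for mast cells and eosinophils, 2.59 for complement and coagulation, 1.09 for interferon-stimulated genes, −1.10 for epithelial junctions and −0.65 for basal epithelium, and log2 changes of 6.08 for PIFO, 4.97 for DNAH9 and 3.99 for CAPS. Complement and coagulation lay just over the limit (0.493155). PIFO, DNAH9 and CAPS are members of the ciliated list, so their marks are not separate from that of its score. Replicate 3 had 4, with −2.14 for antimicrobial peptides and mucosal defence, −2.73 for CCL2, 0.88 for CCNL2 and 0.72 for PARP6, and replicate 6 had 1, −0.44 for LENG8-AS1. For the 4 library measures (total count, genes detected, share of the top 10 genes, mitochondrial share) the rule was applied to levels after gel, not to changes, and marked 0. Their changes were not examined by the rule. In the participant of after PC-6500 replicate 4, genes detected went from 23339 to 26957. The share of the top 10 genes went from 22.2 to 12.4% there.

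Camera called 11 lists for the change with PC-6500 against that with placebo. As given above, 74 of 100 splits of the participants reached 11 lists, with a median of 17 in the other splits, so the calls do not establish a difference between the gels. The adjusted p was 0.000271 for mucins and glycosylation, 0.000411 for smooth muscle and pericytes and for the unfolded protein response, 0.00283 for immediate early genes, and 0.0150 for glycogen and glycolysis and for histones. It was 0.0210 for apoptosis, cell cycle and fibroblasts, and 0.0448 for endothelium and ribosomal proteins. With an estimated correlation the adjusted p was 0.254 for mucins and glycosylation and 0.819 for the others.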

How the results depend on the processing

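The fits with the columnar score as covariate, those without the 3 participants with a columnar-rich library, and the estimated correlation together with another list setting were chosen after the data were seen, and the other settings were fixed before the data were examined. Counts of called genes stayed at 0 in edgeR for PC-6500 and over all participants under every alternative run in edgeR or limma. Arm labels taken from the time point put all 12 participants under PC-6500. That setting is the pooled comparison itself (0 called, 1223 genes at an unadjusted p under 0.05) and adds no separate check. Over the counts that answer a comparison, 156 recomputed values stayed within 1.5 times and 66 did not. Many of the 156 were 0 against 0, among them placebo scores that could not pass and the pooled count taken over for the time point labels. Among named genes 3133 kept direction and side of the threshold, 34 gained a call and 10 turned. Among scores 389 kept both and 43 turned. Lists called with all participants kept both 287 times, lost the call 113 times and turned 10 times, while lists not called gained 53 calls after PC-6500, 11 after placebo and 49 in the difference. These list tallies leave out the estimated correlation together with another list setting, under which 0 lists were called. Either lane alone, with at least 13439045 and 12684163 counts per library, called at most 1 gene in each of the 4 comparisons within participants. The 3 placebo pairs left wide intervals, within a 2-fold change for 11106 of 18642 genes (59.6%) after placebo and for 10199 of 18652 (54.7%) for the difference. These intervals use the spread shared by both arms. Fitted alone, the placebo arm gave 0 called genes, with 935 at an unadjusted p under 0.05. The block for the participant changed no count of called genes, which without pairing was 0 in each of 4 comparisons (570 genes at an unadjusted p under 0.05 for PC-6500, 760 for placebo, 357 for the difference and 746 over all participants), and without the block 2 list calls after PC-6500 ended, immediate early genes (adjusted p = 0.0765) and ciliated cells (0.0895). Without the block lists gained calls too, after PC-6500 fibroblasts (0.0279) and macrophages, neutrophils, lymphatic endothelium and smooth muscle (0.0426 each), all lower, after placebo epidermal proteases (0.0413, higher), and in the difference squamous differentiation (0.0256) and macrophages (0.0351), both lower. Genes at an unadjusted p under 0.05 in edgeR also moved by over 1.5 times from 790 for PC-6500, 1053 for placebo, 617 for the difference and 1223 over all participants. With the columnar covariate they were 1302, 1610, 966 and 1920 in that order, with the squamous minus fibroblast covariate 1799 for PC-6500, 1086 for the difference and 2162 over all participants, and without the 3 participants 1895 for placebo. The 3 were all in the PC-6500 arm, so the placebo pairs behind the 1895 were those of the main fit. Where a value changed below, the cause was not tested unless stated.

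DESeq2 called 3 genes for PC-6500, 95 for placebo, 26 for the difference, 34 over all participants and 49 between baselines, where edgeR called 0. After placebo edgeR called 2 genes without a filter on low counts (MUC20 and GRB7, adjusted p = 0.0413), 1 with a CPM filter (GRB7, 0.0368), 1 on the first lane alone (GRB7, 0.0423), 2 with the columnar covariate (MUC20 and GRB7, 0.00638) and 5 without the 3 participants (GRB7, PIK3IP1, MUC20 and GALNT12 at 0.0223 and SOX7 at 0.0455). The 3 participants left out were all in the PC-6500 arm, so the placebo pairs were the same in that fit. The log2 changes of GRB7 (1.03) and MUC20 (1.54) stayed close to those of the main fit. What differed was the spread shared by both arms, with the scaling and the filter, so the 5 calls tell nothing about columnar tissue in placebo biopsies. For the difference it called 1 with the covariate (MUC20, log2 −1.65, 0.0257).

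For lists, an estimated correlation and fry each called 0 in the 3 comparisons, and so did the estimated correlation together with no replicate block, RLE size factors, the CPM filter, the columnar covariate, the 3 participants left out or each participant left out (lowest adjusted p 0.415 after PC-6500, 0.478 after placebo and 0.168 in the difference). After PC-6500 the covariate gave 13 calls, the CPM filter 3 and leaving out the 3 participants 15, and for the difference the covariate gave 17 and leaving them out 7. With the CPM filter T and NK cells, heat shock and immediate early genes (0.0510 each) were not called after PC-6500, nor cell cycle after placebo (0.0529) or ribosomal proteins in the difference (0.134), and with the covariate heat shock (0.0667) and ribosomal proteins in the difference (0.0573) were not. Without the 3 participants immediate early genes turned to higher after PC-6500 (0.0173), endothelium after placebo was at 0.0725, and the difference lost immediate early genes (0.435), endothelium (0.1696), fibroblasts (0.131), apoptosis (0.124) and glycogen and glycolysis (0.0678).

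Some values turned sign. Without the 3 participants EGR1, at −0.56 after PC-6500 with all 9, was at 0.18, the epithelial junctions score at 0.081 after PC-6500 and 0.016 in the difference, and the cytokine score at 0.10 after PC-6500. With the median over members the epithelial junctions score was at 0.033 and the cytokine score at 0.022 after PC-6500, and in the difference the HIV list score at 0.13, the NF-kB score at 0.091 and the squamous score at −0.35, which was at −0.0018 with RLE size factors. PIFO was at 0.13 with the covariate, 0.60 with the squamous minus fibroblast covariate, 1.01 with limma voom, 0.22 with a random effect, 2.13 without the block and 0.29 on the second lane.

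Leaving out each participant in turn, genes at an unadjusted p under 0.05 ranged from 511 (without replicate 3) to 1859 (without replicate 4) for PC-6500, 497 (without after placebo replicate 3) to 1390 for placebo, 372 (without after placebo replicate 3) to 886 for the difference, 864 to 2848 (without after PC-6500 replicate 4) over all participants and 593 (without baseline replicate 4) to 1520 between baselines. It gave 5 to 24 called lists after PC-6500, the 24 (5 higher, 19 lower) without after PC-6500 replicate 4, 4 to 13 after placebo, the 4 without after placebo replicate 3, and 8 to 17 for the difference. Called genes ranged from 0 to 1 for the difference (MUC20, without after PC-6500 replicate 4) and from 0 to 1 between baselines (1 gene with near-identical copies, without baseline replicate 4). Adjusted p ranged, with a change of direction, from 1.53e-05 to 0.0248 for ciliated cells after PC-6500. After placebo it ranged from 1.32e-06 to 0.260 for cell cycle, 1.51e-05 to 0.0292 for endothelium and 5.96e-07 to 0.449 for squamous differentiation. In the difference it ranged from 3.39e-06 to 0.233 for cell cycle, 3.58e-05 to 0.117 for endothelium, 0.000175 to 0.345 for fibroblasts, 0.000185 to 0.951 for glycogen and glycolysis and 5.29e-06 to 0.571 for smooth muscle. CAPS ranged from −0.0098 (without replicate 4) to 0.54 and PIFO from −0.67 to 0.12. Score changes after PC-6500 ranged from −0.69 (without replicate 4) to 0.82 (without replicate 3) for columnar epithelium, −0.058 to 0.12 for epithelial junctions, −0.18 to 0.034 for interferon-stimulated genes and −0.32 to 0.17 for cytokines. After placebo they ranged from −0.21 to 0.089 for columnar epithelium, −0.13 to 0.25 for epithelial junctions, −0.20 to 0.13 for the HIV list, −0.14 to 0.031 for NF-kB targets and −0.36 to 0.68 for squamous differentiation. For the difference they ranged from −0.64 to 0.87 for columnar epithelium, −0.26 to 0.13 for epithelial junctions, −0.27 to 1.19 for fibroblasts, −0.31 to 0.013 for the HIV list, −0.014 to 0.35 for interferon-stimulated genes and −0.13 to 0.0099 for the mitochondrial list. They ranged from −0.38 to 1.82 for smooth muscle, −0.51 to 0.55 for squamous differentiation and −0.32 to 0.058 for T and NK cells.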

Other observations

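The genes in this part were chosen only after their values were seen, and their values come from the tests of the comparisons above, which were not. CD4, the receptor that HIV binds, was at 16.7 CPM at baseline and 18.3 CPM after gel (higher in 4 and lower in 5 of 9 participants, with a fitted log2 difference of −0.03, SE 0.20, opposite in sign to the difference of the means) and the chemokine receptor CXCR4 at 8.62 and 7.21 CPM (−0.53, SE 0.51). After placebo the interferon-induced chemokine CXCL10 was at 4.99 CPM against 15.04 CPM at baseline (log2 difference −1.43) and LCN2, which encodes an iron-binding antimicrobial protein, at 1402 against 666 CPM (1.04), with CXCL10 lower and LCN2 higher in 3 of 3 participants. None of these 4 genes passed an adjusted p of 0.05 in edgeR.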
